A study of Rattus norvegicus with 4 samples.

How the data were processed

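The data were 4 single-colour microarrays of rat miRNAs (Toray 3D-Gene, Cy5 label), 2 from hepatocytes and 2 from LSECs of untreated rats. The deposited scanner tables gave each spot's median intensity as linear brightness, per the file headers from scans at 3 gains merged onto a common scale, with the background still in. No spot stood at the scanner's upper limit (0 spots). Each array held 3200 spots: 761 rat miRNA probes with 1 spot each (3 of them naming several miRNAs), 1664 blank spots, 513 spots without a probe, 16 spike control spots, 166 spots named S-Probe, and 80 quality and negative control spots. Quality marks set by the scanner software touched 0 miRNA spots.

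The authors also deposited a table of processed intensity values, whose scale was not stated in words. Set against the scanner tables, its values equalled the spot median minus the array's trimmed blank mean, times a constant for each array that put the median of the listed miRNAs at 25. The ratio varied by 0.152 to 0.291% (coefficient of variation) within an array. Values were missing below about the blank mean plus 2 SD, and 563 and 597 miRNAs were listed for the hepatocyte arrays and 680 and 662 for the LSEC arrays. These scaled levels are linear intensities, and the probe-to-probe differences in brightness they carry were not compared with each other.

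The analysis started from the spot medians. Background was corrected by normexp, fitted on all spots, with an offset of 50, and the 761 miRNA probes were quantile-normalized between arrays (R 4.3.3, limma 3.58.1). The deposited background column was not used for this, because across miRNA probes it correlated with the spot's own log2 intensity with r = 0.964 to 0.982. A miRNA counted as detected on an array where its spot exceeded the mean plus 2 SD of the blank spots, after leaving out the top and bottom 5% of them. The 652 miRNAs detected on both arrays of at least 1 cell type were tested. Blank spots had an SD of 1.71 and 2.63 intensity units on the hepatocyte arrays and 1.15 and 1.24 on the LSEC arrays, and the brightest miRNA spots read 21459, 38063, 43655 and 44808. Replicated control spots had a median coefficient of variation of 5.42, 7.15, 4.41 and 8.54% on the 4 arrays.

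LSEC minus hepatocyte differences were fitted with limma (lmFit, eBayes) on the log2 scale and called at a Benjamini-Hochberg adjusted p under 0.05. For a miRNA detected on both arrays of 1 cell type and neither of the other, only a bound on the fold was given. The miRNAs named were, among calls without overlap between cell types, the 8 with the largest difference per direction among those detected on all arrays and the 5 with the largest bound per direction (only 3 existed for hepatocytes). To these came both arms of miR-122, miR-126a, miR-511, miR-192 and miR-194 as checks of the labels, and up to 4 leading members of each list with members called in the opposite direction. Further miRNAs are said to have been chosen after their values were seen. In all, 24 lists of miRNAs by cell type, family or cluster were fixed, of which 23 had at least 3 tested members. They covered hepatocyte, lipid and energy metabolism, endothelial, leukocyte and Kupffer cell, stellate and mesenchymal, cholangiocyte and epithelial, erythroid, muscle and neural miRNAs, miR-511, and the families and clusters of miR-17-92, miR-23-27-24, miR-99/100 and miR-125, let-7 and miR-98, miR-10, miR-15/16, miR-29, miR-30, miR-34 and miR-449, miR-130 and miR-301, miR-181, miR-101, Dlk1-Dio3 and miR-290-295. Each was tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg over the 23 lists, and again with an estimated correlation. The latter takes its degrees of freedom from the 4 arrays, which left it little power. Each was also tested with fry, which asks whether members differ at all, not whether they differ more than other miRNAs. The 5p minus 3p difference of a hairpin was computed within each array and tested with limma over 131 hairpins. The samples, the tests, the lists, the rule for naming miRNAs and most alternatives were fixed before the data were examined.

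Alternatives changed the background correction, the scaling between arrays, the detection filter, the limma options, the replicate number as a block, and each array in turn. Scaling by the spike control spots, subtraction of the deposited background column, and scaling by the median without an offset were added after seeing the data. On simulated data with the fitted spread, 652 miRNAs and 200 of them changed, limma called 90.1% of log2 changes of 0.5, 97.2% of changes of 1, 99.3% of changes of 2 and 99.9% of changes of 4, and 3.62% of calls were unchanged miRNAs (50 simulations). The simulated spread was independent between miRNAs, which real arrays need not be. Changes were added to values already normalized, and a small further set was shifted for a list test. These rates therefore leave out errors from the background correction, the offset and the scaling between arrays. Host genes and neighbouring genes were read from the RefSeq annotation of the GRCr8 assembly by miRBase names. These matched 72 of 74 named hairpins for host genes and 386 of 436 hairpins for neighbouring genes. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).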

Results

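MicroRNAs (miRNAs), short RNAs that repress the messenger RNAs they pair with, were measured in hepatocytes and in liver sinusoidal endothelial cells (LSECs) of untreated male Sprague-Dawley rats aged 10 weeks. Hepatocytes are the parenchymal cells of the liver, and LSECs are the fenestrated endothelial cells that line its capillaries. The series held 4 samples, 2 of each cell type, and each sample was hybridised to its own single-colour array with 761 rat miRNA probes. The comparison asks which miRNAs mark each of these cell types, a question tied to the search for circulating markers of injury to hepatocytes or to LSECs. The labels do not say whether the samples of a cell type came from separate animals. Each p-value therefore sets a difference against the spread between these samples alone, after normalization and partly pooled over miRNAs by limma. The number of arrays limits the precision of every value below. Errors are standard errors of the fitted log2 difference, LSEC minus hepatocyte, from 2 arrays per cell type.

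More miRNAs were detected in LSECs than in hepatocytes. A probe counted as detected where its signal exceeded the mean of the array's blank spots by 2 SD. By this limit 563 and 596 miRNAs were detected on the hepatocyte arrays, and 680 and 660 on the LSEC arrays. Of the 761 miRNAs, 482 were detected on all 4 arrays and 30 on no array. Blank spots averaged 79.5 and 92.1 intensity units on the hepatocyte arrays and 70.9 and 71.8 units on the LSEC arrays. The detection limit was 83.0 and 97.4 units on the hepatocyte arrays and 73.2 and 74.2 on the LSEC arrays. A miRNA thus needed more signal above the blanks to be detected in hepatocytes, and the detection counts also reflect this. The median signal above the blanks of the miRNAs detected on all arrays was 12.7 and 20.9 units in hepatocytes and 29.1 and 30.8 units in LSECs. The spike control spots ran the other way, at 18049 and 30476 units above the blanks on the hepatocyte arrays and 12410 and 12284 units on the LSEC arrays. Across the 652 miRNAs tested, normalized log2 values correlated with r = 0.994 between the hepatocyte arrays, r = 0.996 between the LSEC arrays, and r = 0.720 to 0.733 between arrays of different cell types. These are correlations across miRNAs, which are not independent replicates.

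Both arms of miR-122 and of miR-126a, miR-192-5p and miR-194-5p separated the arrays as the labels do. The level of miR-122-5p, the dominant miRNA of hepatocytes, was 51468 and 59303 in the authors' scaled values for hepatocytes and 168.7 and 109.9 for LSECs, a fitted difference of -8.25 ± 0.10. Its other arm, miR-122-3p, differed by -5.89 ± 0.09. The level of miR-126a-3p, an endothelial miRNA whose gene lies within the endothelial gene Egfl7 in the GRCr8 rat annotation, was 46.5 and 81.3 in hepatocytes and 67716 and 63106 in LSECs, a difference of 8.41 ± 0.15. Its 5p arm differed by 5.98 ± 0.07. Quantile normalization gives miRNAs of equal rank the same value on every array. The normalized SD was thus 0 for miR-122-5p, miR-192-5p and miR-802-5p between hepatocyte arrays. It was also 0 for miR-126a-3p and miR-27a-3p between LSEC arrays. The errors of these miRNAs hold no spread from that cell type beyond what limma pools. For miR-192-5p and miR-194-5p, clustered miRNAs enriched in liver and gut, the differences were -5.34 ± 0.05 and -5.73 ± 0.04. Their 3p arms differed by -0.91 ± 0.04 for miR-192-3p, with authors' levels of 65.1 and 71.3 against 7.8 and 5.8, and by -0.60 ± 0.13 for miR-194-3p. The miR-194-3p call (adjusted p = 0.0343) ended without LSEC array 1 (adjusted p = 0.230) or LSEC array 2 (adjusted p = 0.268), and without normalization (adjusted p = 0.631) or in the authors' values (0.0750), and under spike scaling its difference was 0.26. The gene of miR-511 lies within Mrc1, which encodes the mannose receptor carried by LSECs and macrophages. Its 3p arm was detected on 1 hepatocyte array, at 9.7, and on both LSEC arrays, at 989.1 and 893.6, a difference of 2.97 ± 0.05 (adjusted p = 2.7e-05). It was called the other way, at -0.63 (adjusted p = 0.0227), with the background column of the deposited files subtracted. Its 5p arm differed by 0.11 ± 0.05 (adjusted p = 0.178), with no call.

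**Figure D1:**
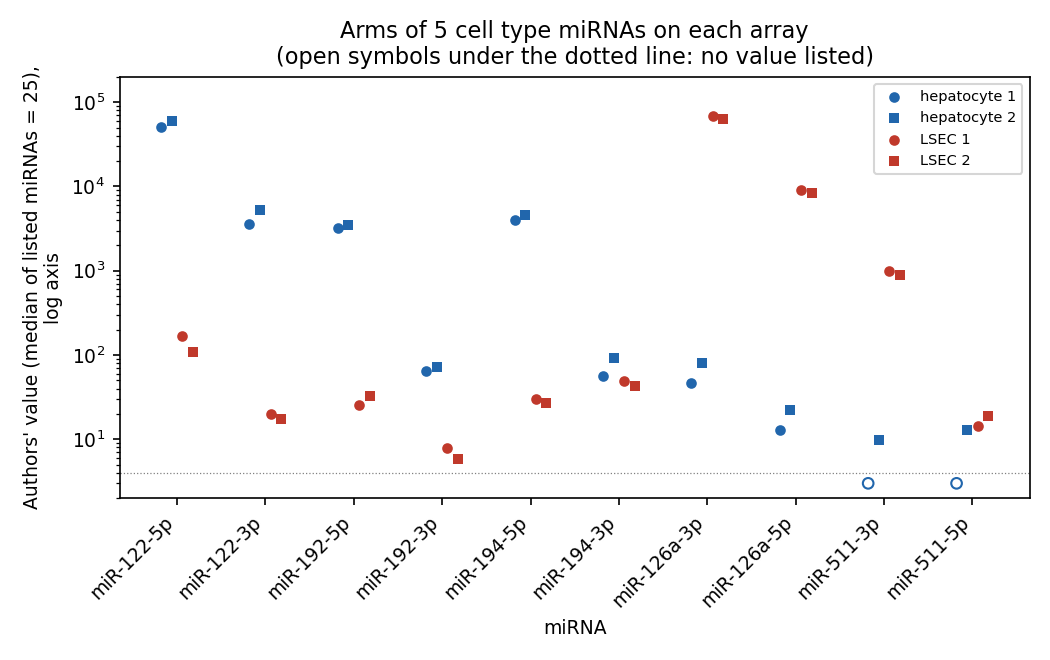
The authors' scaled value (log axis, median of the listed miRNAs = 25) of both arms of miR-122, miR-192, miR-194, miR-126a and miR-511 on each of the 4 arrays, with hepatocytes in blue and LSECs in red. Open symbols mark arrays for which no value was listed; miR-122-5p reads 51468 and 59303 in hepatocytes against 168.7 and 109.9 in LSECs.

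Of the 652 miRNAs tested, 241 differed between LSECs and hepatocytes in limma at an adjusted p under 0.05. Higher levels were called in LSECs for 121 and in hepatocytes for 120, and 316 had an unadjusted p under 0.05. At least 2-fold differences were called for 89 miRNAs, 46 higher in LSECs and 43 higher in hepatocytes. The arrays of the cell types did not overlap for any of the 241. Selecting calls by their difference over their spread all but ensures this, so it is no support for them. Uncalled miRNAs such as miR-511-5p were free of overlap too. With 2 samples against 2, chance gives such a separation for a share of 0.333 of miRNAs. For a single miRNA an exact permutation test of 2 against 2 samples has a smallest 2-sided p of 0.333, so the calls rest on the spread limma pools over miRNAs. Without LSEC array 1 the count was 109, with 57 higher in LSECs and 52 in hepatocytes, and without LSEC array 2 it was 116, with 60 and 56. Folds are on a log2(intensity + 50) scale, which makes them smaller for dim miRNAs, so the authors' scaled levels are given beside some of them.

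The split between the directions depended on how the arrays were scaled to each other. Quantile normalization, which gives every array the same distribution, called 50.2% of the differing miRNAs higher in LSECs. Scaling by the median gave 153 higher in LSECs and 225 in hepatocytes, and scaling by the 75th percentile gave 137 and 308. Without normalization the counts were 150 and 27. Scaling by the spike control spots gave 438 and 21. The authors' values gave 196 and 111 among the 482 miRNAs they allowed to be tested. They also lack the offset, so their counts and median do not reflect scaling alone. The median difference over the miRNAs tested moved to -0.15 with the 75th percentile, to 0.28 in the authors' values and to 0.29 with the spikes. Of the 121 miRNAs called higher in LSECs, 99 had a value under all 6 other scalings, and 92 of these kept that direction under each. Of the 120 called higher in hepatocytes 116 had such values, and 36 kept it. Most of that loss came under spike scaling, which moves every miRNA toward the LSEC side and where 40 of the 120 kept their direction. Without normalization 94 of the 120 kept it, and in the authors' values 95 of 116 did. Subtracting the background column of the deposited files left 17 calls; that column rose with the spot's own brightness, with r = 0.964 to 0.982 across miRNA probes on the log2 scale.

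**Figure D2:**
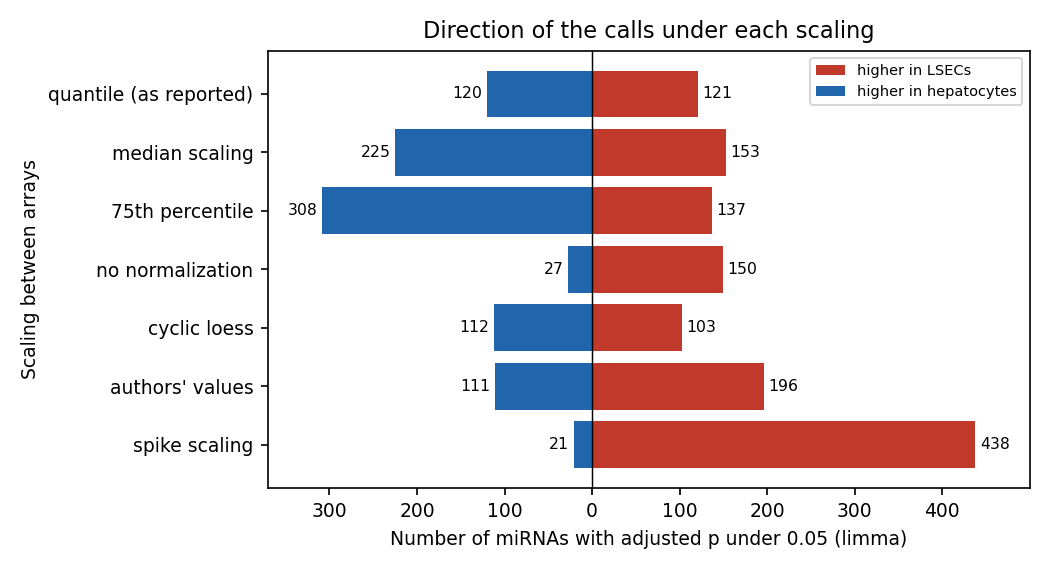
Number of miRNAs called higher in LSECs (red, to the right) and higher in hepatocytes (blue, to the left) at an adjusted p under 0.05 under each of 7 ways of scaling the arrays. The hepatocyte side runs from 21 under spike scaling to 308 under the 75th percentile, and the LSEC side from 103 under cyclic loess to 438 under spike scaling. The authors' values also lack the offset and cover 482 of the 652 miRNAs.

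The miRNAs with the largest excess in LSECs, among those detected on all 4 arrays, were both arms of miR-126a, miR-10a-5p, miR-150-5p, miR-23a-3p, miR-10b-5p, miR-27a-3p and miR-450a-5p. After miR-126a came miR-10a-5p, encoded in a Hox gene cluster, at 4.20 ± 0.04, with authors' levels of 21.1 and 20.7 in hepatocytes and 2835 and 2843 in LSECs. The lymphocyte miRNA miR-150-5p differed by 3.70 ± 0.08, with 16.9 and 12 in hepatocytes and 1676 and 1874 in LSECs. The clustered miR-23a-3p and miR-27a-3p differed by 2.99 ± 0.09 and 2.41 ± 0.07, and the level of miR-23a-3p was 347.4 and 359.7 in hepatocytes and 7133 and 7144 in LSECs. For miR-10b-5p, whose gene lies within Hoxd4 in GRCr8, the difference was 2.60 ± 0.07, and for miR-450a-5p, encoded on chromosome X, it was 2.40 ± 0.06. Adjusted p for these 8 miRNAs ranged from 1.84e-05 to 0.000104, and each kept its call without any 1 array. With the background column subtracted miR-10a-5p was called the other way, at -0.84 (adjusted p = 0.0103).

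The largest excesses in hepatocytes were those of both arms of miR-122, miR-194-5p, miR-192-5p, miR-148a-3p, miR-101b-3p, miR-31a-5p and miR-483-5p. The difference was -4.21 ± 0.05 for miR-148a-3p, a liver miRNA that represses the low-density lipoprotein receptor, with authors' levels of 1454 and 1687 in hepatocytes and 61.7 and 68.5 in LSECs. For miR-101b-3p, whose gene lies within Rcl1, it was -4.09 ± 0.07, with 1626 and 1659 in hepatocytes and 72.5 and 92.8 in LSECs. At -3.89 ± 0.05, miR-31a-5p read 763.5 and 854.6 in hepatocytes and 13.3 and 11.3 in LSECs. The difference for miR-483-5p, whose gene lies within Igf2, was -3.37 ± 0.08, with 623.8 and 793.2 against 50.1 and 44.1. Adjusted p for the 8 ranged from 1.47e-05 to 6.01e-05, and each kept its call without any 1 array and its direction under every scaling. With the background column subtracted miR-122-3p was called the other way, at 0.85 (adjusted p = 0.0236), and miR-31a-5p lay at 0.12 with no call (adjusted p = 0.349).

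**Figure D3:**
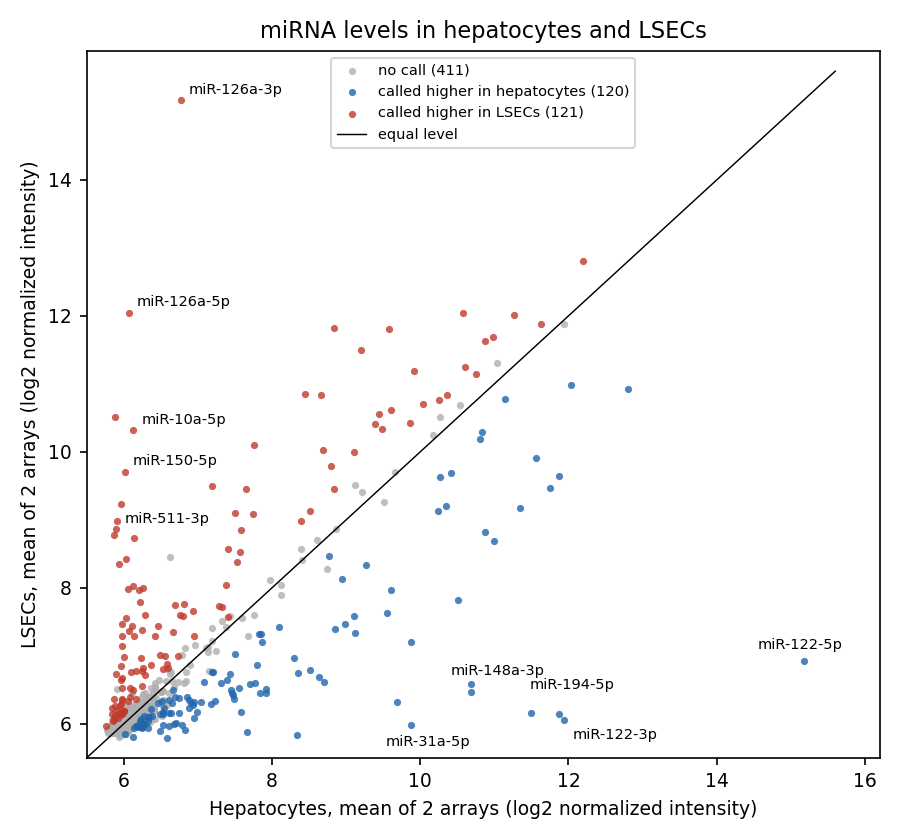
Mean normalized log2 intensity of the 652 tested miRNAs in hepatocytes (horizontal) and LSECs (vertical), 2 arrays each, with 121 miRNAs called higher in LSECs in red, 120 called higher in hepatocytes in blue and 411 without a call in grey. The black line marks equal levels; miR-126a-3p lies 8.41 log2 units above it and miR-122-5p falls below it with a difference of -8.25.

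Some miRNAs were seen in one cell type and not in the other. Detection on both LSEC arrays and neither hepatocyte array was found for 47 miRNAs, 9 of them called, and the reverse for 5 miRNAs, 3 of them called. These counts depend on the detection limit, which lay further above the blanks on the hepatocyte arrays. At a limit of 5 SD the LSEC count was 145. At the top stood miR-199a-3p, a miRNA of mesenchymal cells, which was at least 7.27-fold higher in LSECs (authors' levels 892.1 and 773.6). It was followed by miR-542-3p at least 1.77-fold, miR-10a-3p at least 1.37-fold, miR-146a-3p at least 1.27-fold and miR-3068-5p at least 1.25-fold higher. In hepatocytes, miR-802-5p, a miRNA linked to hepatic glucose metabolism, was at least 5.6-fold higher (270.7 and 267.6), and miR-137-3p and miR-203b-3p were at least 1.65-fold and 1.21-fold higher. Bounds set the mean of the bright cell type against the dim cell type's own signal or the lowest detected signal of its arrays, whichever was higher, and hold for quantile normalization. The difference for miR-802-5p was -2.51, against -1.82 without normalization and -1.48 under spike scaling, and miR-203b-3p had no call without normalization (adjusted p = 0.161). Among these, leaving out LSEC array 1 ended the calls of miR-10a-3p (adjusted p = 0.0547), miR-146a-3p (0.0790), miR-3068-5p (0.0925), miR-137-3p (0.0925) and miR-203b-3p (0.0836). Leaving out LSEC array 2 ended those of miR-146a-3p (0.0591), miR-3068-5p (0.130), miR-137-3p (0.0918) and miR-203b-3p (0.0745), and leaving out hepatocyte array 2 that of miR-3068-5p (0.0586). The count for LSECs was 81 without hepatocyte array 1 and 114 without hepatocyte array 2, and the count for hepatocytes ran from 11 to 15 without any 1 of the arrays (11 and 15 without hepatocyte arrays 1 and 2, 15 and 12 without LSEC arrays 1 and 2).

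Among the lists fixed beforehand, hepatocyte miRNAs had the smallest camera p. Of 15 tested, 12 were higher in hepatocytes and 0 in LSECs (12 when adjusted over the list alone), led by the arms of miR-122, miR-194-5p and miR-192-5p. The camera test gave an adjusted p = 7.89e-07, against an adjusted p = 0.383 with an estimated correlation. None of the 23 lists tested held with an estimated correlation. That version takes its degrees of freedom from the 4 arrays, which leaves it little power. Its results, here and below, therefore cannot decide whether correlated members account for a camera call. The estimate lay below the preset correlation for hepatocyte miRNAs (-0.0048). It lay above the preset for the lipid and energy (0.087), leukocyte and Kupffer cell (0.090) and cholangiocyte and epithelial (0.020) lists. For the other lists that passed camera it lay below. Under spike scaling 2 of the 12 called hepatocyte miRNAs turned to the LSEC side. Of 9 miRNAs tied to lipid and energy metabolism, 6 were higher in hepatocytes and 0 in LSECs (6 when adjusted over the list alone). They included miR-378a-3p at -1.92 ± 0.06 and miR-378a-5p at -1.05 ± 0.05, from a hairpin within the metabolic coactivator gene Ppargc1b, as well as miR-378b at -1.79 ± 0.06 and miR-33-5p at -0.88 ± 0.07, the latter from within the sterol regulator gene Srebf2. Under spike scaling all 4 lay on the LSEC side, at 0.27, 0.051, 0.19 and 0.067 in the order named, and with the background column subtracted miR-378a-3p lay at 0.31. Without normalization miR-378a-3p (-0.51, adjusted p = 0.115), miR-378a-5p (-0.46, adjusted p = 0.0749) and miR-33-5p (-0.39, adjusted p = 0.176) had no call. For this list camera gave an adjusted p = 0.0255 (adjusted p = 0.433 with an estimated correlation). That call was lost without hepatocyte array 1 (adjusted p = 0.0903) and in 9 other settings, over a range of 0.0155 to 0.773, and miR-33-5p lost its own without LSEC array 1 (adjusted p = 0.0511).

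The list of endothelial miRNAs did not pass camera, though 1 of its members, miR-126a-3p, had the largest LSEC excess of all miRNAs tested. Of 18 tested, 6 were higher in LSECs and 2 in hepatocytes (7 and 2 when adjusted over the list alone), with a camera adjusted p = 0.180 (adjusted p = 0.591 with an estimated correlation). It passed fry (adjusted p = 0.0040), which does not set members against other miRNAs. Beside the arms of miR-126a stood miR-322-5p at 3.27 ± 0.15, the rat counterpart of the hypoxia-responsive human miR-424, and miR-322-3p at 0.97 ± 0.20. The call of miR-322-3p ended without hepatocyte array 1 (adjusted p = 0.143), hepatocyte array 2 (0.130) or LSEC array 1 (0.0627) and with cyclic loess (0.0716), and with the background column subtracted it lay at -0.18. On the hepatocyte side, miR-221-3p differed by -0.52 ± 0.05 but by 0.37 without normalization, 0.21 in the authors' values and 1.07 under spike scaling, and miR-503-5p by -0.48 ± 0.10 but by 0.080 without normalization and 0.62 under spike scaling. Calls for miR-221-3p ended without LSEC array 1 (adjusted p = 0.0762) or 2 (0.0650), and for miR-503-5p without LSEC array 1 (0.170), LSEC array 2 (0.258) or hepatocyte array 2 (0.0740). Median scaling ended both calls (adjusted p = 0.857 and 0.124), as it did without an offset (0.269 and 0.140), and that of miR-503-5p ended in the authors' values (0.789), with plain subtraction (0.0519) and with the replicate block (0.0537). The list for the Mrc1 intron held only the arms of miR-511, 1 of 2 higher in LSECs (1 when adjusted over the list alone), and was too small to test.

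Leukocyte and Kupffer cell miRNAs were higher in the LSEC samples. Kupffer cells are the macrophages of the liver sinusoids. Of 15 tested, 10 were higher in LSECs and 0 in hepatocytes (10 when adjusted over the list alone). The largest was miR-146a-5p, an NF-kB-induced miRNA that restrains inflammatory signalling, at 4.62 ± 0.06, detected on 1 hepatocyte array at 9.0 and on the LSEC arrays at 3243 and 3078. It was followed by miR-150-5p at 3.70 ± 0.08, miR-146b-5p at 3.08 ± 0.05 and the haematopoietic miR-142-5p at 1.73 ± 0.23. Camera gave an adjusted p = 0.000941 (adjusted p = 0.405 with an estimated correlation), which was 0.0648 under spike scaling and 0.352 with the background column subtracted, over a range of 0.000162 to 0.352. The call for miR-142-5p ended without hepatocyte array 1 (adjusted p = 0.0859) or 2 (0.0907).

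Stellate and mesenchymal cell miRNAs went both ways. Of 10 tested, 5 were higher in LSECs and 2 in hepatocytes (6 and 2 when adjusted over the list alone), with a camera adjusted p = 0.180 (adjusted p = 0.433 with an estimated correlation). Fry gave an adjusted p = 0.0052. The camera test passed with the 75th percentile (0.0265) and without normalization (0.0467), over a range of 0.0265 to 0.458. Higher in LSECs were miR-199a-3p, miR-199a-5p at 1.75 ± 0.07 and miR-143-3p at 1.90 ± 0.20, the last a miRNA of contractile and perivascular cells. Its call ended without hepatocyte array 1 (adjusted p = 0.0600) or 2 (0.0586). Higher in hepatocytes were miR-483-5p and miR-143-5p, the latter at -0.93 ± 0.04. Without normalization miR-143-5p had no call (-0.15, adjusted p = 0.702), and it lay at 0.48 under spike scaling and at 0.12 with the background column subtracted.

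Cholangiocyte and epithelial miRNAs were higher in the hepatocyte samples. Cholangiocytes line the bile ducts. Of 18 tested, 9 were higher in hepatocytes and 0 in LSECs (10 when adjusted over the list alone), with a camera adjusted p = 0.00228 (adjusted p = 0.383 with an estimated correlation). The call was lost only with the background column subtracted (0.396), over a range of 2.11e-06 to 0.396. The differences were -1.89 ± 0.04 for miR-375-5p and -1.40 ± 0.09 for miR-203a-3p, a miRNA of stratified epithelium. They were -0.80 ± 0.15 for miR-200b-3p, which maintains the epithelial state, and -0.64 ± 0.04 for miR-183-3p. Authors' levels of miR-375-5p were 9614.5 and 12255 in hepatocytes and 3925 and 4077 in LSECs. Those of miR-375-3p were 11 and 20.9 in hepatocytes and 9.1 and 8.3 in LSECs. Probe specificity was not measured here. The 3p arm of miR-375 had no call, at -0.09 ± 0.07 (adjusted p = 0.343), though it was called with median scaling (-0.23, adjusted p = 0.0202), with the 75th percentile (-0.29, 0.0105), without hepatocyte array 1 (-0.20, 0.0440) and with median scaling without an offset (-1.29, 0.0466). Under spike scaling 2 of the 9 turned, among them miR-183-3p at 0.16, and miR-375-5p was left without a call (adjusted p = 0.310). Without normalization neither miR-183-3p (adjusted p = 0.353) nor miR-200b-3p (0.0597) had a call. With the background column subtracted miR-203a-3p lay at 0.14 and miR-200b-3p at 0.049, and the call of miR-200b-3p ended without LSEC array 1 (adjusted p = 0.203) or 2 (0.217).

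Several seed families and clusters were higher in LSECs. Of the 11 miRNAs of the miR-23-27-24 clusters, known for roles in vessel growth, 8 were higher in LSECs and 0 in hepatocytes (8 when adjusted over the list alone; camera adjusted p = 0.000941, adjusted p = 0.383 with an estimated correlation). Beside miR-23a-3p and miR-27a-3p these included miR-24-3p at 2.30 ± 0.04 and miR-23b-3p at 2.22 ± 0.07. In the miR-10 family 3 of 3 were higher in LSECs (3 when adjusted over the list alone; camera adjusted p = 0.00531, adjusted p = 0.383 with an estimated correlation). Of 9 tested in the miR-15/16 family, which restrains cell division, 5 were higher in LSECs and 0 in hepatocytes (5 when adjusted over the list alone; camera adjusted p = 0.00391, adjusted p = 0.383 with an estimated correlation). They were led by miR-497-5p at 1.60 ± 0.05, miR-16-5p at 1.47 ± 0.05 and miR-195-5p at 1.33 ± 0.12, the last losing its call without LSEC array 1 (adjusted p = 0.0641) or 2 (0.0561). Of 7 tested in the miR-130 and miR-301 family 4 were higher in LSECs and 0 in hepatocytes (4 when adjusted over the list alone; camera adjusted p = 0.0449, adjusted p = 0.427 with an estimated correlation), with miR-130a-3p at 2.35 ± 0.15, miR-130b-3p at 1.30 ± 0.04 and miR-301a-3p at 0.70 ± 0.04. With the background column subtracted miR-301a-3p lay at -0.029. Signals of near-identical family members are not independent where a probe also binds a sister miRNA, which was not measured here. The calls of the miR-10 and miR-15/16 families were lost under spike scaling (0.0648 for each) and with the background column subtracted (0.891 and 0.396), over ranges of 0.00307 to 0.891 and 0.00208 to 0.396. The call of the miR-130 and miR-301 family was lost in 13 of 20 settings, among them the fits without hepatocyte array 1 (0.0511), LSEC array 1 (0.0510) and LSEC array 2 (0.0615), over a range of 0.0277 to 0.396.

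**Figure D4:**
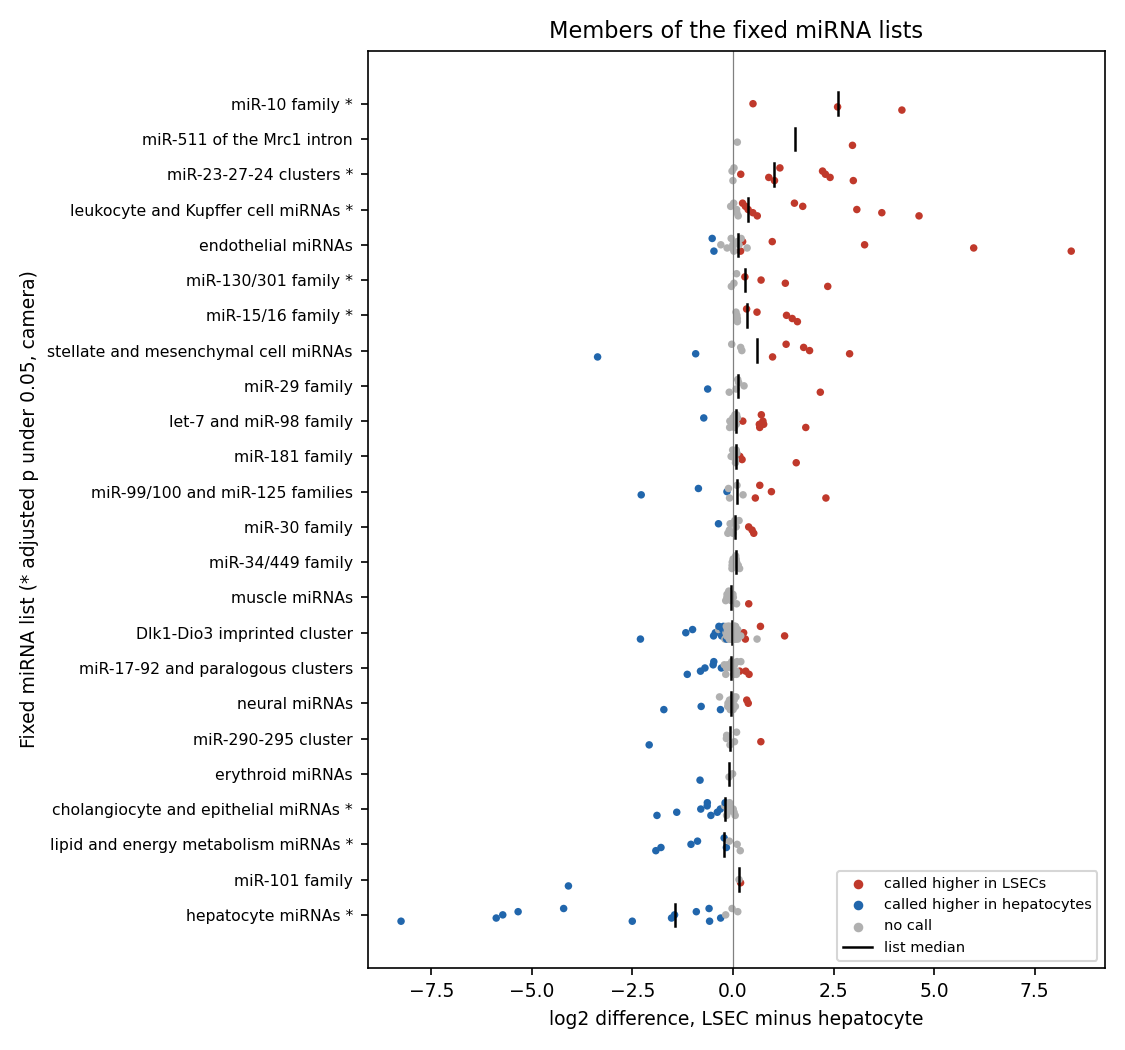
Fitted log2 difference, LSEC minus hepatocyte (horizontal), of each member of the 24 fixed lists, coloured by call, with the list median as a black bar; an asterisk marks the 8 lists with a camera adjusted p under 0.05. Hepatocyte miRNAs lie furthest to the left, down to -8.25 for miR-122-5p, and miR-126a-3p lies furthest to the right at 8.41; called members of the lipid, epithelial and hepatocyte lists partly turn to the LSEC side under spike scaling.

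The other lists did not pass camera. Each had members called in at least 1 direction except the miR-34 and miR-449 family. Of its 9 members 0 were called (0 when adjusted over the list alone, camera adjusted p = 0.562), against 241 of all 652 miRNAs tested. Of 3 erythroid miRNAs 1 was higher in hepatocytes, miR-451-5p at -0.82 ± 0.16 (no call without normalization, -0.39, adjusted p = 0.0610, or under spike scaling, -0.023, adjusted p = 0.853; 0.034 with the background column subtracted), and of 9 muscle miRNAs 1 was higher in LSECs, miR-133c at 0.39 ± 0.05. Of 16 neural miRNAs 2 were higher in LSECs, among them miR-128-3p at 0.38 ± 0.04, and 3 in hepatocytes, with miR-138-2-3p the furthest at -1.72 ± 0.09 (no call under spike scaling, -0.084, adjusted p = 0.177). Of 7 miR-29 family members 1 was higher in each cell type, miR-29b-3p in LSECs at 2.17 ± 0.19 and miR-29c-3p in hepatocytes at -0.63 ± 0.14. Of 11 miR-30 family members 3 were higher in LSECs, miR-30d-5p the furthest at 0.51 ± 0.08, and 1 in hepatocytes, miR-30b-5p at -0.36 ± 0.04. Of 19 let-7 and miR-98 family members 7 were higher in LSECs, let-7i-5p the furthest at 1.81 ± 0.24, and 1 in hepatocytes, let-7g-5p at -0.73 ± 0.05. The hepatocyte direction of let-7g-5p, miR-29c-3p and miR-30b-5p was opposite in 5 of the 6 other scalings. Of 10 miR-181 family members 3 were higher in LSECs, miR-181a-5p the furthest at 1.57 ± 0.07. Of 3 miR-101 family members 1 was higher in hepatocytes, miR-101b-3p, and 1 in LSECs, miR-101a-5p at 0.19 ± 0.05; the list's median was 0.15 and its mean -1.25. Of 7 in the miR-290-295 cluster, expressed in early embryos, 1 was higher in hepatocytes, miR-295-5p at -2.09 ± 0.09, and 1 in LSECs, miR-290 at 0.69 ± 0.11. For these 9 lists the counts were equal when adjusted over the list alone. Under at least 1 other scaling 2 of the let-7 calls, 1 of the miR-30 calls and 1 of the miR-181 calls for LSECs turned to the hepatocyte side, and 1 neural call for hepatocytes turned to the LSEC side.

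In the larger clusters, 3 of 21 members of the miR-17-92 and paralogous clusters, which promote proliferation, were higher in LSECs, miR-106b-5p the furthest at 0.40 ± 0.10, and 6 in hepatocytes (3 and 6 when adjusted over the list alone; adjusted p = 0.436). All 6 turned to the LSEC side under spike scaling; miR-19b-3p, at -1.14 ± 0.04, was at 0.49 without normalization, 0.15 in the authors' values and 1.36 under spike scaling, and had no call with median scaling (-0.030, adjusted p = 0.641). Of 66 tested in the imprinted Dlk1-Dio3 cluster 4 were higher in LSECs, miR-494-3p the furthest at 1.28 ± 0.11, and 11 in hepatocytes, miR-487b-3p the furthest at -2.30 ± 0.11 (4 and 9 when adjusted over the list alone; adjusted p = 0.170). Under spike scaling 10 of these 11 turned to the LSEC side, and miR-487b-3p was left without a call (-0.0044, adjusted p = 0.970). In the miR-99/100 and miR-125 families 4 of 11 were higher in LSECs and 3 in hepatocytes (5 and 3 when adjusted over the list alone; adjusted p = 0.858), and 1 of the hepatocyte calls turned under spike scaling.

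For the lists that did not pass, camera's adjusted p was 0.436 for erythroid, 0.630 for muscle and 0.436 for neural miRNAs, 0.483 for the miR-29 family, 0.617 for miR-30, 0.160 for let-7 and miR-98, 0.170 for miR-181, 0.858 for miR-101 and 0.630 for miR-290-295. Every list that passed camera also passed fry. So did let-7 and miR-98 (fry adjusted p = 9.3e-05), miR-99/100 and miR-125 (0.0041), miR-101 (0.0041), miR-290-295 (0.0078), miR-181 (0.012), Dlk1-Dio3 (0.013), miR-17-92 (0.029) and miR-30 (0.029). Fry did not pass miR-34 and miR-449 (0.057), miR-29 (0.073), erythroid (0.12), neural (0.14) or muscle miRNAs (0.64). Other settings brought some lists past camera: let-7 and miR-98 in 4 settings (0.0145 to 0.642), miR-30 in 3 settings (0.0110 to 0.834) and the Dlk1-Dio3 cluster in 5 settings (0.00465 to 0.394). Several single calls named from these lists ended with 1 array fewer, and 10 of them ended whichever LSEC array was left out. The differences were then -0.78 and -0.69 for miR-451-5p, 2.29 and 2.06 for miR-29b-3p and -0.36 and -0.36 for miR-30b-5p. Without LSEC array 1, adjusted p was 0.203 for miR-451-5p, 0.0908 for miR-133c, 0.0681 for miR-128-3p, 0.0562 for miR-29b-3p, 0.213 for miR-29c-3p, 0.108 for miR-30d-5p, 0.0745 for miR-30b-5p, 0.254 for miR-101a-5p, 0.0952 for miR-290 and 0.171 for miR-106b-5p. Without LSEC array 2 it was 0.232, 0.0989, 0.0648, 0.0508, 0.198, 0.0824, 0.0629, 0.267, 0.144 and 0.0698 for the same miRNAs in the same order, and 0.0549 for miR-494-3p. Without hepatocyte array 1 it was 0.0510 for miR-30d-5p, 0.0818 for let-7i-5p, 0.0603 for miR-101a-5p and 0.123 for miR-106b-5p, and without hepatocyte array 2 it was 0.0763 for let-7i-5p, 0.0680 for miR-290 and 0.185 for miR-106b-5p. The call of miR-101a-5p also ended in several other settings, among them median scaling (adjusted p = 0.188), the 75th percentile (0.777) and no normalization (0.353). With plain subtraction those of miR-29c-3p (0.0814), miR-30b-5p (0.127), miR-30d-5p (0.0799) and miR-106b-5p (0.102) ended, and the last also with cyclic loess (0.116). With the background column subtracted let-7i-5p lay at -0.61 and miR-30b-5p at 1.64.

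The arms of a hairpin often changed by unequal amounts. For 131 hairpins both arms were detected on all 4 arrays, and for 80 of them the 5p minus 3p difference changed between the cell types at an adjusted p under 0.05 (limma). The offset shrinks the change of a dim arm more than that of a bright one, so part of this count can come from arm brightness. In the authors' values, which carry no offset, 74 did, and 63 did in both with the same sign. There miR-122 changed by -0.79 (limma adjusted p = 0.0545) against -2.37 with the offset. For let-7g and miR-20a the change turned, to 1.19 and 1.26 from -0.64 and -0.63. For 20 hairpins both arms were called in the same direction, and for 11 in opposite directions. Of these, 3 hairpins were chosen after their values were seen. For miR-125a, a miRNA that represses the ErbB receptors, the 5p arm was higher in LSECs at 2.31 ± 0.27. Its authors' levels were 114.9 and 84.7 in hepatocytes and 1832 and 1147 in LSECs. The 3p arm was higher in hepatocytes at -2.28 ± 0.04, with 3475 and 4504 there and 1533 and 1419 in LSECs. Probe specificity was not measured. The 5p minus 3p difference of miR-125a changed by 4.59 ± 0.25 (adjusted p = 5.87e-05). For miR-143 it changed by -2.83 ± 0.18 (adjusted p = 0.000101), with -0.93 for the 5p arm and 1.90 for the 3p arm. For miR-652 it changed by -2.16 ± 0.09 (adjusted p = 2.29e-05), with -1.64 ± 0.07 for the 5p arm and 0.52 ± 0.04 for the 3p arm. The 5p arms of miR-143 and miR-652 lay on the LSEC side under spike scaling, at 0.48 and 0.54, and miR-125a-3p had no call there (-0.10, adjusted p = 0.310). Neither 5p arm had a call without normalization (-0.15 and -0.36, adjusted p = 0.702 and 0.337). The 5p minus 3p changes of the 3 hairpins kept their sign and call under all 6 other scalings. Except for cyclic loess, these scalings differ from each other by a multiplier per array. Such a multiplier cancels in a difference within an array, apart from the offset, so this is little support. The miR-125a-5p call ended without hepatocyte array 1 (adjusted p = 0.0556) or 2 (0.0680), and that of miR-143-3p too (0.0600 and 0.0586). At a detection limit of 5 SD 38 of 49 hairpins passed, and with the background column subtracted 9 of 131. None of these 3 hairpins was among the 9 (2.55, -0.64 and -1.52 for miR-125a, miR-143 and miR-652, adjusted p = 0.102, 0.639 and 0.216).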

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

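All tests in this part were chosen after the results they bear on were seen. Among control spots that no comparison used, 6 of the 40 S-Probe types read over 100 intensity units above the blanks in both cell types, and 21 were above the blank limit on all 4 arrays; what these probes detect is not given in the sources used here. S-Probe1014 was brighter in LSECs, with 1621 and 2731 units above the blanks on the hepatocyte arrays, 8306 and 9505 on the LSEC arrays, and a log2 difference of 2.08. S-Probe1018 was brighter there too, with a log2 difference of 0.78. S-Probe28, S-Probe27 and S-Probe26 were dimmer in LSECs, with -0.93, -0.91 and -0.91, and S-Probe1019 differed by -0.025.

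The miRNA spots were dimmer on the hepatocyte arrays while the spike control spots were brighter there. Over the 482 miRNAs detected on all arrays the median log2 difference above the blanks, LSEC minus hepatocyte, was 0.66, against -0.93 for the spike control spots, which ranged from -1.31 to -0.54 over the pairs of arrays. A brightness of the whole array shared by spikes and miRNAs predicts a positive spike difference, and the value of -0.93 argues against it as the cause. After scaling by the spikes the median difference was 1.59, so a lower share of miRNA in the labelled hepatocyte RNA may account for it, and so may less RNA labelled per hepatocyte array. These cannot be told apart because the amount of RNA labelled per array is not given in the sources used here.

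Quantile normalization removes such a difference by design, and it called almost as many miRNAs higher in hepatocytes (120) as in LSECs (121). Under spike scaling 40 of the 120 hepatocyte calls kept their direction. That count cannot test the normalization, because the spikes move every miRNA toward the LSEC side. Cyclic loess, which also evens out differences between arrays, called 103 higher in LSECs and 112 in hepatocytes. Scalings that do not even them out in this way gave unequal splits. Examples are 137 and 308 with the 75th percentile and 150 and 27 without normalization. The even split thus depended on the normalization, and the split in the cells cannot be told from these arrays. The spikes report on labelling and hybridisation only if equal amounts were added to each sample, which is not given in the sources used here.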

How the results depend on the processing

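Spike scaling, subtraction of the background column and median scaling without an offset were recomputed beside the other alternatives; these 3 were chosen after seeing the data. Averaging repeat spots by their median was not run, since each miRNA probe had 1 spot. Of the recomputed counts 97 stayed within 1.5 times the reported value and 35 moved further. Of the values recomputed for the named miRNAs, 1617 kept direction and side of the threshold, 174 kept direction and lost the call, 26 gained a call and 51 turned. With replicate number as a block, which the labels do not state to be a pairing (correlation of same-numbered arrays after removing cell type 0.034), 198 miRNAs were called, 196 of them among the 241, with 99 in each direction, 7 lists and 77 hairpins. Leaving out an array in turn gave 109 to 234 calls (57 to 98 higher in LSECs, 52 to 136 in hepatocytes), 59 to 114 miRNAs detected in LSECs only and 11 to 15 in hepatocytes only; a cell type left with a lone array was assumed to vary like the other. Signal over background limits dim miRNAs most: with an offset of 50 their differences shrink, and at a detection limit of 5 SD 145 miRNAs were seen in LSECs only and 38 hairpins passed, of the 49 left to test. Without an offset, at least 2-fold differences numbered 202 (plain subtraction), 205 (authors' values) and 248 (median scaling without an offset), which the missing offset by itself widens. With detection required on all arrays 5 lists passed, with fewer members tested. Where no construction is named, the cause was not tested.

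Changes of scaling or background moved these values. The authors' values and the median without an offset also lack the offset, and the authors' values cover 482 miRNAs. Subtracting the background column changes the background correction, not the scaling. With the median: 378 calls, 225 higher in hepatocytes, let-7g-5p 0.43, miR-29c-3p 0.47, miR-30b-5p 0.40. With the 75th percentile: 445 calls, 308 higher in hepatocytes, and for the same miRNAs 0.20, 0.24 and 0.17. Without normalization: 27 higher in hepatocytes, and 0.95, 0.99 and 0.95, with miR-221-3p 0.37, miR-503-5p 0.080 and miR-19b-3p 0.49. In the authors' values: 196 higher in LSECs, and 0.64, 0.68 and 0.59, with miR-221-3p 0.21 and miR-19b-3p 0.15. With the median and no offset: 0.15, 0.19 and 0.10. With the spikes: 459 calls, 438 higher in LSECs and 21 in hepatocytes, 156 at least 2-fold, 3 lists, and 1.83, 1.86 and 1.85, with miR-19b-3p 1.36, miR-221-3p 1.07, miR-503-5p 0.62, miR-652-5p 0.54, miR-143-5p 0.48, miR-378a-3p 0.27, miR-194-3p 0.26, miR-378b 0.19, miR-501-5p 0.19, miR-183-3p 0.16, miR-33-5p 0.067 and miR-378a-5p 0.051. With the background column subtracted, which removes part of each spot's own signal: 17 calls, 10 higher in LSECs and 7 in hepatocytes, 13 at least 2-fold, 2 lists and 9 hairpins. Turned there were miR-10a-5p (-0.84), miR-122-3p (0.85), miR-511-3p (-0.63), let-7i-5p (-0.61), miR-31a-5p (0.12), miR-378a-3p (0.31), miR-143-5p (0.12), miR-203a-3p (0.14), miR-200b-3p (0.049), miR-451-5p (0.034), miR-30b-5p (1.64), miR-322-3p (-0.18), miR-362-3p (-0.14), miR-532-5p (-0.18), miR-532-3p (-0.24) and miR-301a-3p (-0.029). For the lipid and energy list camera's direction turned there while the median, -0.00081, stayed negative; with the spikes the median was 0.22 and camera's direction stayed. The hepatocyte and miR-23-27-24 lists passed in all 20 alternatives, with adjusted p up to 0.0328 and 0.0441. Neither passed with an estimated correlation (adjusted p = 0.383 for each), a version of camera with too little power here to decide.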

Other observations

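The tests of neighbouring genes were chosen before their results were seen. Their repeat with the brighter arm and the test of leukocyte miRNAs were chosen after. The miRNAs in the first paragraph were chosen after their values were seen.

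The level of miR-450b-5p was higher in LSECs by 2.42 ± 0.06 (log2 ± SE, 2 arrays per cell type), and it was detected on 1 hepatocyte array. Also higher there, miR-362-5p at 1.49 ± 0.06, miR-362-3p at 1.33 ± 0.05, miR-532-5p at 1.15 ± 0.15 and miR-500-3p at 1.12 ± 0.05 come from hairpins that the GRCr8 annotation places within the span of Clcn5, a chloride transporter gene on chromosome X. From within the same gene, miR-501-5p was higher in hepatocytes at -0.39 ± 0.08 (adjusted p = 0.0288), and miR-500-5p (-0.12 ± 0.04), miR-188-5p (0.17 ± 0.05) and miR-188-3p (0.019 ± 0.060) had no call, while miR-501-3p (0.66 ± 0.04) and miR-532-3p (0.86 ± 0.10) were higher in LSECs. The miR-532-3p call ended without hepatocyte array 1 (adjusted p = 0.0618) or 2 (0.0648), and it lay at -0.24 with the background column subtracted. The miR-501-5p call ended without hepatocyte array 2 (adjusted p = 0.0586), LSEC array 1 (0.236), LSEC array 2 (0.196) or normalization (0.625) and with the background column subtracted (0.228), and under spike scaling it lay at 0.19. In other settings miR-500-5p was called higher in hepatocytes 5 times, miR-188-5p higher in LSECs 8 times and miR-188-3p higher in LSECs under spike scaling (0.42, adjusted p = 0.00145). The miR-532-5p call ended without LSEC array 1 (adjusted p = 0.0738) or hepatocyte array 2 (adjusted p = 0.0681), and with the background column subtracted it and miR-362-3p lay at -0.18 and -0.14. Higher in hepatocytes were miR-1188-3p at -2.69 ± 0.05, miR-193a-3p at -2.66 ± 0.06, miR-22-3p at -2.18 ± 0.04 and miR-22-5p at -1.94 ± 0.20. The call of miR-22-5p ended without LSEC array 1 (adjusted p = 0.0802) or 2 (0.0813), and that of miR-22-3p under spike scaling (adjusted p = 0.662).

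Neighbouring miRNA genes, within 10 kb of each other on GRCr8, differed between the cell types by similar amounts. Over 124 neighbouring pairs the mean gap between their log2 differences (means of the tested arms) was 0.45, against 0.60 when hairpins were permuted (1-sided permutation p = 0.0001, the smallest that 10000 permutations can give). Cross-hybridisation between similar sequences is argued against by the 96 pairs of different families (0.50 against 0.63, permutation p = 0.0009), and a shared closeness to the background by the 13 pairs of bright hairpins (0.52 against 0.96, permutation p = 0.0008). Averaging lets opposite arms cancel, as for miR-125a, so the brighter arm was used instead, with permutation p = 0.0002 over all pairs, 0.0032 for different families and 0.0117 for bright hairpins. Shared transcription of neighbours is therefore a candidate explanation, as a hypothesis.

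In the leukocyte list, the arms of miR-142 were brighter on LSEC array 2 than on LSEC array 1 by 0.95 (median log2 ratio), and the median of the 8 other members called higher in LSECs was 0.19, within a range of -0.21 to 0.55. With 2 LSEC arrays and several dim members, these ratios do not decide where the list's excess came from. Leukocytes or Kupffer cells among the LSECs cannot be told apart from expression in LSECs, for miR-142 or for the other members, since no independent marker of those cells was measured.

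Between the LSEC arrays, miR-143-3p and miR-145-5p differed the other way, with log2 ratios of -0.66 and -0.65, while miR-199a-3p differed by -0.07. The ratio was 1.55 for miR-127-3p (25.9 and 75.9 units above the blanks) and -1.29 for miR-335, so shifts as large as that of miR-142 were not limited to leukocyte miRNAs. The level of miR-335 had no call (1.83 ± 0.62, adjusted p = 0.0956) but was called higher in LSECs in 7 other settings, with adjusted p from 0.000244 without normalization to 0.0395 in limma with trend and robust. It had authors' levels of 111.9 and 9.6 on the hepatocyte arrays and 1034 and 382.7 on the LSEC arrays.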
